A study of Drosophila melanogaster with 12 samples.

How the data were processed

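Transcript abundance was measured on Affymetrix Drosophila expression arrays in 12 samples. Wing discs were taken from wandering OreR larvae of instar 3 raised at 25 °C, and S2 cells had been kept for fewer than 30 passages. Cells were sorted by DNA content into a 2C gate (G1) and a 4C gate (G2), and 100 ng of total RNA per sample was amplified with the MessageAmp III kit and labelled with biotin. The groups were wing disc G1, wing disc G2, S2 G1 and S2 G2, with 3 arrays each, numbered 2, 3 and 4 for wing disc and 4, 5 and 6 for S2. The labels do not say whether the arrays of a group came from separate dissections or cultures, so p-values measure the spread between these samples.

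The deposited values are probe set intensities on a linear scale, made by the authors with RMA in R 2.15.2. The background method and the array normalization within RMA are not given in the sources used here. The design written before the data were examined assumed log2 values. The deposited intensity values reach over 28530 on every array, so log2 was taken first, with no other change to the test. Array medians on the log2 scale ran from 4.18 to 4.37, and 40.4% to 42.0% of probe sets had a value of at least 5. Arrays give no counts, and the number of arrays limits the precision.

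The table held 18952 probe sets, of which 183 controls were left out. Of the other 18769 probe sets, 13646 had 1 gene in the platform annotation of 2016, 402 had several and 4721 had none listed. Gene identifiers of 13543 of the 13646 were found in the current gene table, and 0 symbols changed. Probe sets with a log2 value of at least 5 on at least 3 of the 12 arrays were kept, which left 8580 (7415 with 1 gene, 225 with several and 940 with none listed). Each of 6937 genes was followed through its probe set with the highest mean over all arrays. No coordinates were used. Of the 6 genes meant to check the sort, 3 (CycA, stg and polo) have no probe set of their own here and were not analysed here.

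Choices in the rest of this account were made before the data were examined unless stated. A linear model with 1 coefficient per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 3.52 prior degrees of freedom), so that the groups share 1 estimate of the spread. The contrasts were wing disc G2 minus G1, S2 G2 minus G1, the disc change minus the S2 change, and the mean of both disc groups minus the mean of both S2 groups. Tests were two-sided, p-values were adjusted over the 8580 probe sets with the method of Benjamini and Hochberg, and an adjusted p under 0.05 passed. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Overlap by chance was the product of the counts of both contrasts divided by 8580.

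A set of 26 gene lists was fixed beforehand. They cover mitotic entry and exit, spindle and cytokinesis, kinetochore and centromere, condensin and cohesin, centrosome, G1/S regulators, origin licensing, replication fork and nucleotide supply, DNA damage response and cell death, ribosome biogenesis, cytosolic ribosomal proteins, proteasome, oxidative phosphorylation, glycolysis, heat shock and dissociation stress, wing disc patterning, sensory organ precursors, Notch response, adult muscle precursors, tracheal cells, haemocytes, fat body, neurons and glia, antimicrobial and immune genes, ecdysone response, and Hippo pathway and growth control. Some list names were not matched to a probe set of their own and were not tested. Among the mitotic regulators these included CycA, stg, Cdk1, polo, aurA, Wee1, Myt1 and BubR1. The stress list lacked Hsp22, Hsp23, Hsp83 and the Hsp70 genes, and the antimicrobial list lacked AttA, CecA1, Dpt and Dro. Each list was tested against all other genes with camera from limma at its preset correlation of 0.01, adjusted over the 26 lists of a contrast. The test was repeated with an estimated correlation, and members were counted both after adjustment over all probe sets and adjusted over the list alone. Among the marker lists, the disc mean was at least 5 for 9 of 9 muscle precursor genes, 10 of 11 tracheal genes, 15 of 20 haemocyte genes and 10 of 11 antimicrobial genes, and the S2 mean for 4, 4, 16 and 11 of them.

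Genes were named by a rule: in each contrast the 6 largest and 6 smallest changes among genes that passed with complete separation of the arrays, the 3 members with the smallest p of each list that passed, the sort check genes, and the 5 highest and 5 lowest shared changes. Further genes named as examples or exceptions of a list, and the genes with opposite changes, were chosen after their values were seen.

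Same-numbered G1 and G2 arrays were checked for pairing. Their deviations from the group means correlated at 0.31 to 0.52 in all 6 pairs, against -0.50 to 0.01 in the 12 pairs with different numbers. The numbers therefore pair the samples, and a fit with replicate number within cell type as a fixed block was run as an alternative. For disc against S2 the block was random, with a consensus correlation of 0.388.

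Other alternatives were subtraction of array medians, cyclic loess, no filter, a filter at a log2 value of 7, a trended variance, array weights, 1 probe set per gene, the mean of a gene's probe sets for the lists, a fit of the arrays of 1 cell type, and leaving out each array in turn. The estimated correlation combined with the block was chosen after seeing the data. Other splits of the arrays into groups of the same sizes were counted, 10 for each contrast of 3 with 3 arrays and 100 drawn with a fixed seed for disc against S2.

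The fit was tested on simulated data with 8580 probe sets and 100 changed genes of each size. At a true change of 1 it recovered 94% in the disc comparison, 96% in the S2 comparison and 75% in the difference between them, and at 0.5 it recovered 40%, 59% and 11%. There were 4, 4 and 5 false calls. The simulated values were independent normal draws with the spread of the fit, without pairing or correlation between genes. The real same-numbered arrays are paired, so these rates may not hold for them.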

Results

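RNA abundance was measured on Affymetrix Drosophila arrays in cells sorted by DNA content. The G1 fraction came from a 2C gate and the G2 fraction from a 4C gate, which also holds cells in mitosis. Cells came from wing imaginal discs of wandering OreR larvae, the epithelium that forms the adult wing and part of the thorax, or from S2 cells, a cultured line of embryonic origin with features of haemocytes (blood cells). The 4 groups (wing disc G1, wing disc G2, S2 G1 and S2 G2) held 3 arrays each, 12 in all. Median intensity per array was 18.1 to 20.6, which is 4.18 to 4.37 on the log2 scale, and 40.4% to 42.0% of probe sets had a log2 value of at least 5. The tests covered 8580 probe sets that reached this value on at least 3 arrays, and 6937 genes were followed through their brightest probe set. Changes are on the log2 scale, where 1 is a doubling, and are given with the standard error (SE) of the fit at n = 3 arrays per group. The number of arrays limits the precision.

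The comparison of G2 with G1 in the wing disc asked which transcripts differ between the gates in a growing epithelium. The gates hold different cells, so a rise or fall in G2 is a difference between fractions. It need not be a change within a cell. Genes of DNA replication fell in G2. dnk (CG5452), which encodes a deoxyribonucleoside kinase, went from 11.88 ± 0.01 to 9.34 ± 0.14 (SD, n = 3), a change of -2.54 ± 0.09 (adjusted p = 3.4e-08). Orc1 (CG10667), a subunit of the origin recognition complex, went from 8.49 ± 0.27 to 6.19 ± 0.23, a change of -2.30 ± 0.16 (adjusted p = 2.7e-06). Prim1 (CG7108, a primase subunit, -2.25 ± 0.13), CG13690 (-2.25 ± 0.10), Ts (CG3181, thymidylate synthase, -2.23 ± 0.09) and CG4570 (-2.20 ± 0.22) completed the 6 largest falls. The largest rise was that of CG13023, from 4.93 ± 0.26 to 8.45 ± 0.37, which is 3.52 ± 0.21 or 11.5-fold (adjusted p = 1.2e-06). It was followed by CG15353 (2.90 ± 0.38), Ect3 (CG3132, 2.58 ± 0.17), the antimicrobial peptide gene Drs (CG10810, drosomycin, 2.10 ± 0.29), the cuticle protein gene TwdlT (CG5812, 2.04 ± 0.16) and the antimicrobial peptide gene Mtk (CG8175, metchnikowin, 1.96 ± 0.26). CG13023, TwdlT (3.80) and Mtk (4.19) were under 5 in G1, near background, so their size and rank among the rises are limited. Genes were named among the largest changes only where every array of one fraction lay above every array of the other, so their separation is no evidence of its own, here and in the other comparisons.

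Both replication groups fell in disc G2. Of 32 genes of the replication fork and nucleotide supply, 30 fell, 0 rose and 2 did not pass the test, with a median change of -1.35 (31 lower when adjusted over the list alone). Among them were Ts, asf1 (a histone chaperone, -1.49 ± 0.08), RnrL (the large ribonucleotide reductase subunit, -1.91 ± 0.11) and PCNA (the sliding clamp, CG9193), which went from 13.28 ± 0.04 to 11.97 ± 0.06, a change of -1.31 ± 0.12 (adjusted p = 2.1e-05). RfC3 (-0.37) and Psf2 (0.09) were the members that did not pass. Of 14 genes of origin licensing, 12 fell, 0 rose and 2 did not pass (Cdc7 at -0.16 and chif at 0.18), with a median of -1.56 and 12 lower adjusted over the list alone. Orc2 (CG3041) fell by 1.61 ± 0.10, Mcm10 (CG9241) by 1.96 ± 0.14 and Mcm5 by 1.77 ± 0.14. The test of a list against all other genes gave adjusted p = 2.05e-47 for the fork list and 5.01e-21 for licensing. With an estimated correlation between genes these were adjusted p = 0.014 and adjusted p = 0.022, and with replicate number as a block besides, adjusted p = 0.097 and adjusted p = 0.31.

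The G1/S regulators moved in both directions. Of 19 genes, 6 fell and 1 rose (6 lower and 3 higher adjusted over the list alone), with a median of -0.05 and a mean of -0.18. Rbf2 (CG5083) and Rbf (CG7413), both of the retinoblastoma family, fell by 0.97 ± 0.08 and 0.89 ± 0.10. CycE (CG3938), the G1/S cyclin, went from 8.53 ± 0.11 to 7.10 ± 0.13, a change of -1.44 ± 0.15 (adjusted p = 6.5e-05). The list had adjusted p = 0.0355, or adjusted p = 0.48 with an estimated correlation, and 0.0937 with replicate number as a block. It also lost its call with array weights (adjusted p = 0.0628) and without wing disc G1 array 2 (adjusted p = 0.0752) or wing disc G2 array 3 (adjusted p = 0.0547).

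Genes of mitosis changed in both directions. Of 30 genes of the spindle and cytokinesis, 8 rose and 2 fell, with a median of 0.30 (10 higher and 2 lower adjusted over the list alone). Klp67A (CG10923), a mitotic kinesin, rose by 1.17 ± 0.18 (adjusted p = 0.0011), Det (CG12265) by 0.51 ± 0.08, and feo, a protein of the central spindle, by 0.71 ± 0.14. mei-38 (CG14781) fell by 1.21 ± 0.19 (adjusted p = 0.0015). The list had adjusted p = 0.0241, or adjusted p = 0.68 with an estimated correlation, and lost its call without wing disc G1 array 2 (adjusted p = 0.0999) or wing disc G2 array 3 (adjusted p = 0.08). CycB (CG3510), the mitotic cyclin, was 10.19 ± 0.16 in G1 and 10.67 ± 0.02 in G2 (0.47 ± 0.16, adjusted p = 0.078), and passed the test with replicate number as a block (adjusted p = 0.0473). Of 26 regulators of mitotic entry and exit, 2 rose and 1 fell (twe, a Cdc25 phosphatase, -1.16 ± 0.10), against 7 and 1 with the block and 6 and 1 adjusted over the list alone. The mean of twe was under 5 in disc G2 (4.46), so the size of its fall is limited. Without CycA, stg, Cdk1, polo, aurA, Wee1, Myt1 and BubR1, which were not tested, these counts do not cover the main regulators of mitotic entry. Of 17 genes of the kinetochore and centromere, 0 rose and 1 fell (cid, the centromeric histone, -1.40 ± 0.16), against 4 and 1 with the block and also when adjusted over the list alone. These lists did not pass as groups (adjusted p = 0.167 and 0.805). Of 18 centrosome genes, 3 rose and 4 fell (the same counts adjusted over the list alone), with adjusted p = 0.645. Of 13 genes of condensin, cohesin and chromosome structure, 0 rose and 2 fell (also adjusted over the list alone), namely eco (CG8598, a cohesin acetyltransferase, -0.67 ± 0.12) and glu (CG11397, a condensin subunit, -0.56 ± 0.14). That list had a median of -0.13 and adjusted p = 0.0355, or adjusted p = 0.60 with an estimated correlation. Its call was lost with no filter (adjusted p = 0.067) and without wing disc G1 array 3 (adjusted p = 0.101), G2 array 2 (adjusted p = 0.069) or G2 array 4 (adjusted p = 0.0548), and that of glu without any 1 of the 6 disc arrays (highest adjusted p = 0.0993).

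Markers of other cell types moved between the disc fractions. Of 9 adult muscle precursor genes, 5 fell, 0 rose and 4 did not pass, with a median of -1.23 (6 lower and 2 higher adjusted over the list alone). twi (CG2956), a transcription factor of these cells, went from 10.57 ± 0.26 to 9.25 ± 0.35, a change of -1.32 ± 0.17. htl (CG7223), a fibroblast growth factor receptor, fell by 1.48 ± 0.20 and the actin gene Act87E (CG18290) fell by 1.42 ± 0.13. Of 20 haemocyte genes, 5 fell and 0 rose, with a median of -0.42 (6 lower adjusted over the list alone, 7 lower and 1 higher with the block). They included SPARC (CG6378, a collagen-binding protein, -1.59 ± 0.12) and the collagen IV genes vkg (CG16858, -1.62 ± 0.22) and Col4a1 (CG4145, -1.62 ± 0.23). Of 11 tracheal genes, 3 rose and 0 fell, with a median of 0.45 (5 higher adjusted over the list alone, 6 with the block). These were verm (CG8756, a chitin deacetylase, 0.69 ± 0.10), uif (CG9138, 0.73 ± 0.14) and vvl (CG10037, 0.91 ± 0.19). The group tests gave adjusted p = 0.000238 for muscle precursors, 3.68e-05 for haemocytes and 0.00353 for trachea. With an estimated correlation they were adjusted p = 0.22, adjusted p = 0.12 and adjusted p = 0.22. Of 2 fat body genes 1 fell (FASN1, -0.63 ± 0.16), and of 5 genes of neurons and glia 1 rose (moody, 1.24 ± 0.18) and 1 fell (nrv2, -0.55 ± 0.13), with adjusted p = 0.645 and 0.92 for the lists (1 higher and 1 lower in each adjusted over the list alone).

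Genes that pattern the wing disc rose as a group at the preset correlation, but not with an estimated correlation. The rise stood beside the fall of the muscle precursor markers (median -1.23) and the haemocyte markers (median -0.42). Whether the gates hold equal shares of the regions of the disc was not tested. Of 39 patterning genes, 8 rose and 2 fell, with a median of 0.26 (14 higher and 3 lower adjusted over the list alone). eyg (CG10488), a transcription factor of the Pax family, went from 6.57 ± 0.15 to 8.05 ± 0.09, a change of 1.49 ± 0.09 (adjusted p = 1.8e-06). The GATA factor gene pnr (CG3978) rose by 0.96 ± 0.14 and fj (CG10917), a Golgi kinase of planar polarity, by 0.57 ± 0.10. bab2 and ct fell (-0.67 ± 0.15 and -0.67 ± 0.19). The list had adjusted p = 0.0106, or adjusted p = 0.48 with an estimated correlation. Of 10 genes of sensory organ precursors, 3 rose and 1 fell, against 3 and 2 adjusted over the list alone. The proneural genes ac and sc rose by 1.64 ± 0.14 and 1.39 ± 0.16 and Brd by 1.22 ± 0.20, while nvy fell by 1.15 ± 0.28. Of 6 genes of the Notch response, E(spl)m4-BFM rose by 1.70 ± 0.31, and E(spl)m6-BFM and bib fell by 1.51 ± 0.17 and 1.09 ± 0.26 (1 higher and 2 lower also adjusted over the list alone). Of 11 antimicrobial and immune genes, 4 rose and 0 fell (also adjusted over the list alone), namely Drs, Mtk, AttD (1.91 ± 0.36) and DptB (0.34 ± 0.09). Mtk and AttD were under 5 in disc G1 (4.19 and 4.85), so the sizes of their rises are limited. These 3 lists did not pass as groups (adjusted p = 0.167 for each).

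Few genes of growth and metabolism moved. Of 58 oxidative phosphorylation genes, 1 fell (Cyt-c1, CG4769, -0.28 ± 0.08) and the median was -0.12 (0 adjusted over the list alone, 4 lower with the block). The list had adjusted p = 5.85e-06, or adjusted p = 0.53 with an estimated correlation. Of 33 cytosolic ribosomal protein genes, 1 fell (RpS5b, CG7014, -0.56 ± 0.16) and the median was -0.03 (0 adjusted over the list alone). In the disc, and also in S2, 29 of the 33 had a mean of at least 13. Array maxima were 14.80 to 14.95, so a change in these genes is hard to see. That list had adjusted p = 0.0355, or adjusted p = 0.71 with an estimated correlation. Its direction turned after cyclic loess (adjusted p = 0.584), and the call was lost after subtraction of array medians (adjusted p = 0.127), with no filter (adjusted p = 0.0687), with array weights (adjusted p = 0.0637) and without wing disc G1 array 4 (adjusted p = 0.137) or G2 array 2 (adjusted p = 0.138). The calls of Cyt-c1 and RpS5b were lost without 9 and 10 of the 12 arrays in turn (highest adjusted p = 0.143 and 0.17). In 34 genes of ribosome biogenesis and 14 heat shock and dissociation stress genes, limma called 0 members, against 4 and 1 at an unadjusted p under 0.05. The stress list lacked Hsp22, Hsp23, Hsp83 and the Hsp70 genes, which were not matched to a probe set of their own. A difference in dissociation stress is therefore not excluded. Of 14 ecdysone response genes limma also called 0 (2 unadjusted), and 6 rose with the block, which also called 2 heat shock genes (1 higher and 1 lower). Of 32 proteasome genes 1 fell (Uch-L5, -0.27 ± 0.08, against 1 higher and 1 lower with the block), of 10 glycolysis genes 1 rose (Glut1, 0.57 ± 0.16, against 2 with the block), and of 21 genes of the Hippo pathway and growth control 1 rose (jub, 0.29 ± 0.08), against 4 with the block. Of 18 genes of the DNA damage response and cell death, Ku80 rose by 0.77 ± 0.16 and egr fell by 1.19 ± 0.27, against 3 higher and 4 lower with the block. Adjusted over the list alone, 3 of these last genes were higher and 3 lower, 1 glycolysis gene was higher, and 0 genes passed in the other 5 of these lists. The 7 lists did not pass as groups, with adjusted p from 0.167 to 0.645.

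Across the wing disc comparison 902 of 8580 probe sets passed, 446 higher and 456 lower in G2, of which 62 rose and 153 fell at least 2-fold. By gene, 376 rose and 391 fell. With replicate number as a block the count was 1626 (987 higher and 639 lower), and without wing disc G1 array 4 it was 601. The balance of directions turned with the scaling, to 502 higher and 402 lower after subtraction of array medians and 365 higher and 494 lower after cyclic loess. Of the 902 probe sets 28 had a disc mean under 5.

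**Figure D1:**
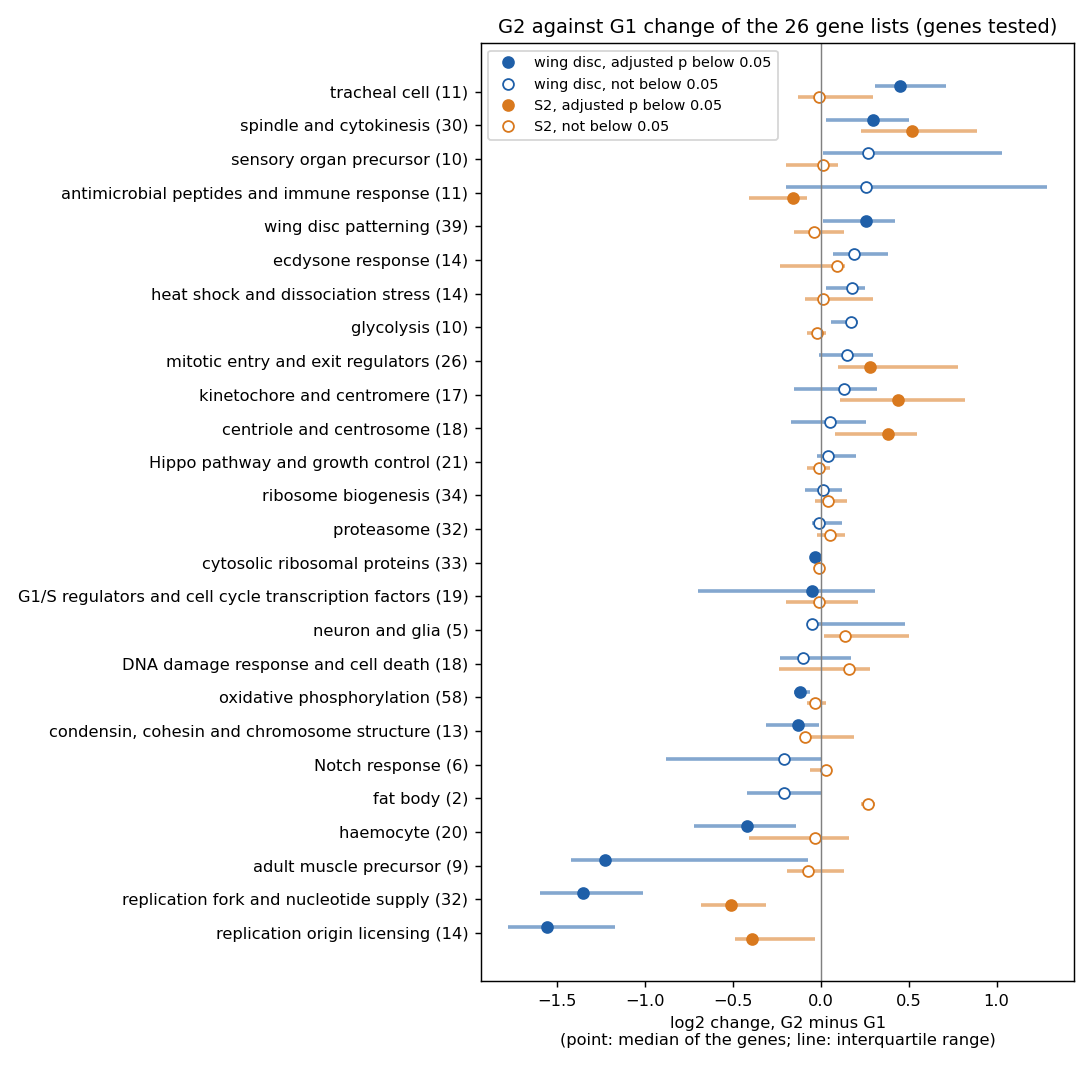
Median log2 change, G2 minus G1, of the genes of each of the 26 lists in wing disc (blue) and S2 (orange), with bars from the lower to the upper quartile of the list's genes. Filled points mark lists with adjusted p under 0.05 at the preset correlation, and the largest falls are those of origin licensing (-1.56) and the replication fork (-1.35) in the disc.

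In S2 cells the comparison of G2 with G1 asked the same question in a cultured line. Many genes of mitosis rose and many of replication fell. Pvf1 (CG7103), a secreted growth factor, had the largest rise, from 6.15 ± 0.81 to 8.29 ± 0.19 (2.14 ± 0.36, adjusted p = 0.0043). Klp67A rose from 7.75 ± 0.32 to 9.52 ± 0.27 (1.76 ± 0.18, adjusted p = 0.00033), and jumu (CG4029, a forkhead factor, 1.72 ± 0.23), squ (CG4711, 1.63 ± 0.15), the spindle orientation gene mud (CG12047, 1.63 ± 0.19) and Msr-110 (CG10596, 1.50 ± 0.19) followed. In S2 G1, mud (4.27) and Msr-110 (4.81) were under 5, near background, so their size and rank among the rises are limited. The largest falls were CG8620 (-1.50 ± 0.24), dnk (-1.43 ± 0.09, from 12.48 ± 0.09 to 11.06 ± 0.06), CG7142 (-1.37 ± 0.21), CG42369 (-1.35 ± 0.23), CG14545 (-1.33 ± 0.17) and WRNexo (CG7670, -1.32 ± 0.14).

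The mitotic regulator, spindle, kinetochore and centrosome lists rose in S2 G2 at the preset correlation, and none passed with an estimated correlation. Of 26 regulators of mitotic entry and exit, 12 rose and 0 fell, with a median of 0.28 (13 higher adjusted over the list alone). pim (CG5052), the securin, rose by 1.07 ± 0.09 (adjusted p = 0.00019), the checkpoint kinase gene Mps1 (CG7643) by 0.99 ± 0.10 and Sse (CG10583), the separase, by 0.87 ± 0.11. CycB went from 9.39 ± 0.28 to 10.39 ± 0.26 (1.0 ± 0.16, adjusted p = 0.0028). Of 30 spindle and cytokinesis genes, 16 rose and 0 fell, with a median of 0.52 (19 higher adjusted over the list alone), Klp67A, mud and the augmin gene dgt5 (CG8828, 0.87 ± 0.10) among them. Of 17 kinetochore genes, 10 rose and 0 fell, with a median of 0.44 (11 higher adjusted over the list alone), such as Spc105R (CG11451, 0.98 ± 0.14), Kmn1 (CG1558, 0.90 ± 0.13) and Zwilch (CG18729, 0.82 ± 0.12). Of 18 centrosome genes, 7 rose and 1 fell (ana2, -0.50 ± 0.12), with a median of 0.38 (10 higher and 1 lower adjusted over the list alone). The risers included Cep135 (CG17081, 1.26 ± 0.16), Plp (CG33957, 0.66 ± 0.13) and Sas-4 (CG10061, 0.73 ± 0.15). The adjusted p was 3.6e-07 for mitotic regulators, 7.78e-10 for the spindle, 7.2e-06 for kinetochores and 0.00421 for centrosomes. With an estimated correlation the first 3 each had adjusted p = 0.38 and the centrosome list adjusted p = 0.82. The centrosome call was also lost without S2 G1 array 6 (adjusted p = 0.186).

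Replication genes fell in S2 G2 as well. Of 32 fork and nucleotide genes, 19 fell and 1 rose (RfC3, 0.63 ± 0.16), with a median of -0.51 (25 lower and 1 higher adjusted over the list alone). Ts fell by 1.26 ± 0.09 (adjusted p = 7.7e-05), dUTPase (CG4584) by 0.82 ± 0.08, asf1 by 0.71 ± 0.08 and PCNA by 0.67 ± 0.12 (from 12.70 ± 0.10 to 12.03 ± 0.27, adjusted p = 0.0051). Of 14 licensing genes, 4 fell and 1 rose, with a median of -0.39 (8 lower and 2 higher adjusted over the list alone, 6 and 2 with the block). Orc5 (CG7833) fell by 0.51 ± 0.10 and Mcm6 (CG4039) by 0.45 ± 0.10, while Cdc6 (CG5971), which loads the replicative helicase, rose by 0.82 ± 0.18. The adjusted p was 5.35e-16 for the fork list and 0.0132 for licensing, or adjusted p = 0.33 and adjusted p = 0.82 with an estimated correlation. Without S2 G2 array 4 the licensing list had adjusted p = 0.156 and Mcm6 adjusted p = 0.056, and without S2 G2 array 6 Cdc6 had adjusted p = 0.056. In a fit of the S2 arrays alone Orc5, Cdc6 and Mcm6 had adjusted p = 0.0621, 0.0601 and 0.0848. CycE went from 8.31 ± 0.19 to 7.54 ± 0.31 (-0.77 ± 0.15, adjusted p = 0.0082). The 19 G1/S regulators, of which 3 rose and 4 fell (4 and 4 adjusted over the list alone), did not pass as a group (adjusted p = 0.782).

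Of the remaining lists, 1 passed in S2. Of 11 antimicrobial and immune genes, 1 fell (PGRP-LB, CG14704, -0.77 ± 0.16, also over the list alone), 0 rose and the median was -0.16, against 3 lower with the block. That list had adjusted p = 0.0479, or adjusted p = 0.62 with an estimated correlation. It lost its call after cyclic loess (adjusted p = 0.0824), with no filter (adjusted p = 0.0682), and without S2 G1 array 4 (adjusted p = 0.185), G1 array 5 (adjusted p = 0.0538), G1 array 6 (adjusted p = 0.0543) or G2 array 6 (adjusted p = 0.167). The call of PGRP-LB was lost without either of 2 arrays (highest adjusted p = 0.0522). The other 19 lists, G1/S regulators included, did not pass (adjusted p from 0.325 to 0.977). In condensin and cohesin genes barr (0.91 ± 0.15) and Cap-G (0.73 ± 0.14) rose and eco fell (-0.48 ± 0.12), against 3 higher and 2 lower adjusted over the list alone and also with the block, and the list's median of -0.09 and mean of 0.08 differed in sign. In DNA damage and cell death genes lok rose by 0.69 ± 0.11 and grp by 0.40 ± 0.10, and Dcp-1, Dark and tefu fell by 0.48 ± 0.09, 0.42 ± 0.09 and 0.46 ± 0.12 (4 higher and 4 lower adjusted over the list alone and also with the block). Of 10 glycolysis genes Glut1 fell by 0.94 ± 0.16, against 2 higher and 2 lower with the block. For the 20 haemocyte genes and 11 tracheal genes limma called 0, against 4 and 2 at an unadjusted p under 0.05 and 5 and 2 with the block. Among 9 muscle precursor genes 1 rose (Ama, 0.36 ± 0.08), against 2 with the block. Among 39 patterning genes limma called 1 higher (zfh2) and 1 lower (ci), against 3 and 4 with the block. The S2 means of ci (3.98 and 3.57) were under 5 and those of zfh2 (4.45 and 5.02) close to it, so no size is read from them. Of 5 genes of neurons and glia moody rose by 0.72 ± 0.18 and nrv2 by 0.50 ± 0.13, and of 14 heat shock and dissociation stress genes Hsp27 rose by 0.52 ± 0.13, GstD1 by 0.35 ± 0.10 and stv fell by 0.67 ± 0.16 (the same counts adjusted over the list alone). Tif-IA rose by 0.47 ± 0.08 among 34 ribosome biogenesis genes, and ATPsynbeta by 0.39 ± 0.11 among 58 of oxidative phosphorylation. In the cytosolic ribosomal, proteasome, sensory organ, Notch, fat body, ecdysone and Hippo lists limma called 0 genes, against 1, 9, 1, 0, 0, 0 and 1 at an unadjusted p under 0.05 and 1, 2, 0, 0, 0, 2 and 0 with the block.

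Across the S2 comparison 828 of 8580 probe sets passed, 526 higher and 302 lower in G2, of which 45 rose and 26 fell at least 2-fold. By gene, 468 rose and 267 fell. The share of calls that were higher was 63.5%, but 48.0% after cyclic loess (389 higher and 422 lower). Of the 828 probe sets 27 had an S2 mean under 5. With replicate number as a block the count was 1577 (939 higher and 638 lower). In a fit of the S2 arrays alone it was 413, and without S2 G1 array 4 or S2 G2 array 4, 5 or 6 it was 493, 545, 506 or 500. Without S2 G1 array 6, which had the lowest array weight (0.24), it was 1088.

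**Figure D2:**
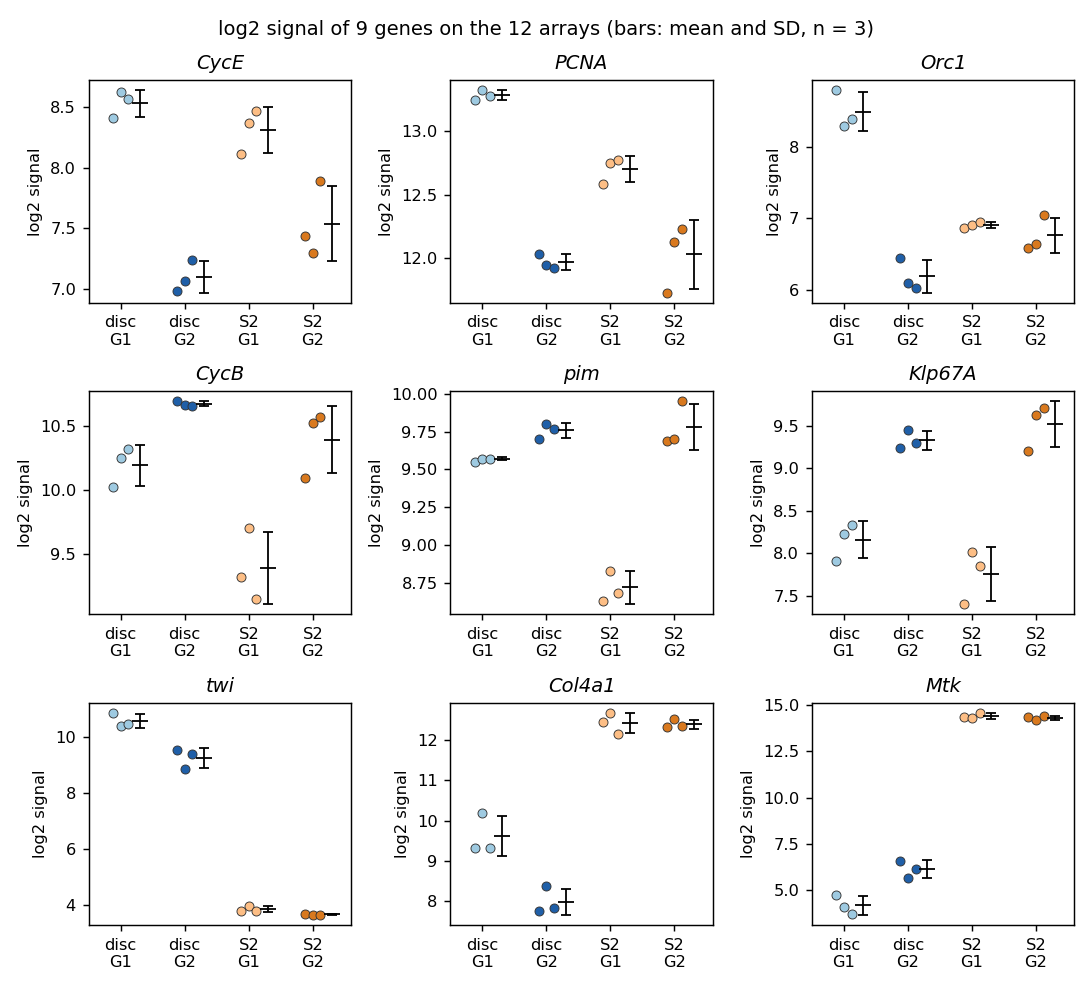
Log2 signal of 9 genes on each of the 12 arrays, by group, with bars for the mean and SD (n = 3). CycE, PCNA and Orc1 lie lower in disc G2 than in disc G1, CycB, pim and Klp67A lie higher in S2 G2 than in S2 G1, and twi, Col4a1 and Mtk differ between the disc fractions.

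Changes were shared between disc and S2 more often than independent lists of these sizes would give. In both, 100 probe sets rose (27.3 by chance) and 108 fell (16.1 by chance), 208 in all, while 21 moved in opposite directions (43.7 by chance). The split of directions depended on the scaling, with 124 shared rises and 87 shared falls after subtraction of array medians and 71 and 144 after cyclic loess. Without S2 G2 array 5 the shared count was 138, with replicate number as a block it was 471, and in separate fits per cell type it was 124. Genes with the largest shared falls were dnk, Ts, WRNexo (-2.04 ± 0.14 in the disc and -1.32 ± 0.14 in S2), CG14545 (-1.99 ± 0.17 and -1.33 ± 0.17) and UK114 (CG15261, -1.97 ± 0.20 and -1.31 ± 0.20), the last 2 ending under 5 in disc G2 (4.16 and 4.41). The largest shared rises were Klp67A, sofe (CG1655, 1.54 ± 0.15 and 1.24 ± 0.15), squ (1.12 ± 0.15 and 1.63 ± 0.15), CG11125 (1.14 ± 0.20 and 1.38 ± 0.20) and nesd (CG10722, 0.97 ± 0.15 and 1.48 ± 0.15). Among the opposite changes, mus101, a replication and checkpoint protein, fell in the disc (-1.13) and rose in S2 (0.45), Cdc6 likewise (-1.01 and 0.82), and CG15282 rose in the disc (1.29) and was lower in S2 G2, but with S2 means under 5 (4.67 and 4.00). Across the 8580 probe sets, which are not independent replicates, the log2 changes had a Pearson correlation of 0.289 and a Spearman correlation of 0.275.

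**Figure D3:**
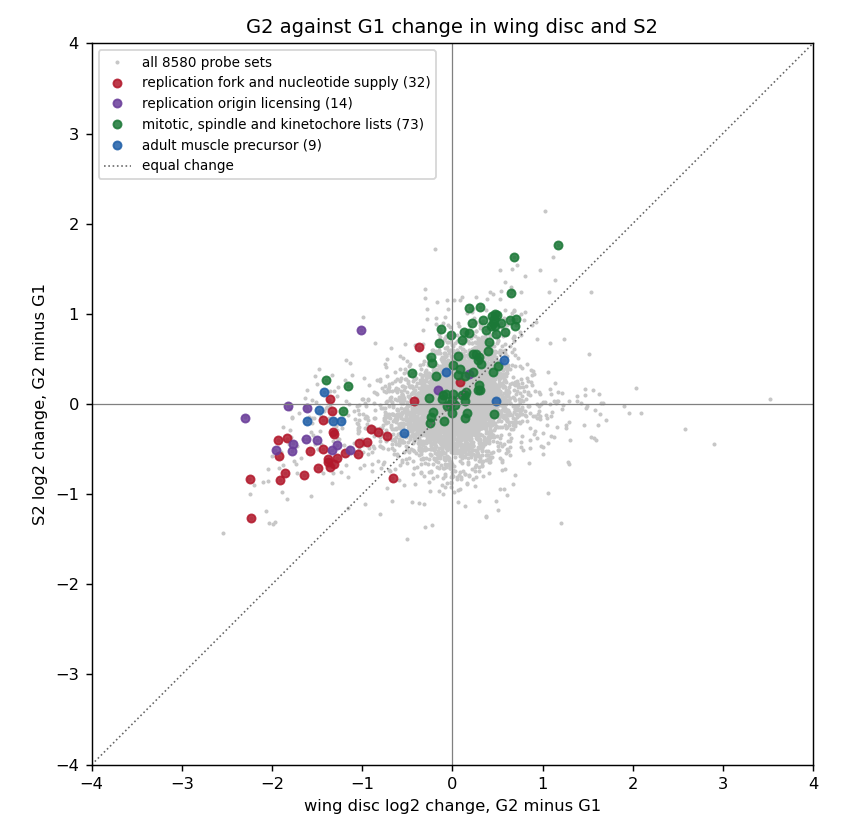
Log2 change, G2 minus G1, in S2 against that in wing disc for the 8580 tested probe sets (grey), with replication fork, origin licensing, mitotic and muscle precursor genes coloured and a dotted line where both changes are equal. Replication genes lie further down in the disc (medians -1.35 and -1.56) than in S2 (-0.51 and -0.39).

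A test of the difference, the disc change minus the S2 change, asked which parts of the G2 against G1 difference depend on the cell type. Replication genes fell further in the disc. Orc1 had a difference of -2.15 ± 0.23 (adjusted p = 0.00056), with -2.30 in the disc and -0.15 in S2, and Cdc6 had -1.83 ± 0.25 (adjusted p = 0.0018). spidey (CG1444, -1.97 ± 0.20), jumu (-1.90 ± 0.33), CG9593 (-1.87 ± 0.31) and Sox100B (CG15552, -1.84 ± 0.27) were the other large negative differences. The largest positive ones were CG13023 (3.47 ± 0.29), CG15353 (3.34 ± 0.53), Ect3 (2.86 ± 0.24), Drs (2.20 ± 0.42), Mtk (2.05 ± 0.37) and slf (CG3244, 2.00 ± 0.22). In S2, CG13023, CG15353, slf, CG9593 and Sox100B were under 5 in both fractions and Ect3 was close to it (5.05 and 4.77), while Drs and Mtk were at 13.69 to 14.40, near the array maxima. The differences of these 8 genes therefore restate the disc change, and their order is not read.

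Of 14 licensing genes, 11 had a more negative change in the disc (13 adjusted over the list alone) and 0 a more positive one, with a median difference of -1.24. dup (CG8171), which acts in helicase loading, had -1.81 ± 0.24 and Orc2 -1.56 ± 0.14. Of 32 fork genes, 22 were more negative in the disc (30 adjusted over the list alone) and 0 more positive, with a median of -0.82, such as Prim2 (CG5553, -1.44 ± 0.19), Caf1-105 (CG12892, -1.41 ± 0.15) and Ts (-0.97 ± 0.13). These lists had adjusted p = 2.25e-17 and 1.22e-25, each adjusted p = 0.047 with an estimated correlation, and adjusted p = 0.40 and adjusted p = 0.27 with an estimated correlation and the block. PCNA (-0.64 ± 0.17, adjusted p = 0.051) and CycE (-0.67 ± 0.21, adjusted p = 0.11) did not pass, but did with the block (adjusted p = 0.0149 and 0.0282). CycB did not pass (-0.53 ± 0.22, adjusted p = 0.23). Of 19 G1/S regulators, 3 were more negative and 1 more positive, with a median of -0.31 (6 and 2 adjusted over the list alone, 5 and 2 with the block). Rbf2 had -0.81 ± 0.11, and mip130 (CG3480, -0.67 ± 0.16) and Cdk4 (CG5072, 0.45 ± 0.11) lost their calls without 8 and 11 of the 12 arrays in turn (highest adjusted p = 0.0967 and 0.112). The list had adjusted p = 0.0196, or adjusted p = 0.30 with an estimated correlation, and 0.0647 without S2 G1 array 6.

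Mitotic groups had more negative changes in the disc than in S2 at the preset correlation, and none passed with an estimated correlation. Of 26 mitotic regulators, 5 were more negative (7 adjusted over the list alone) and 0 more positive, with a median of -0.19. twe (CG4965, -1.36 ± 0.14), pim (-0.87 ± 0.13) and CycB3 (CG5814, a mitotic cyclin, -0.78 ± 0.15) had the smallest p of this list. twe was under 5 in both S2 fractions (3.73 and 3.93), so its difference restates its disc fall. Of 30 spindle genes, 3 were more negative, with a median of -0.28 (6 adjusted over the list alone and also with the block). They were borr (CG4454, -0.79 ± 0.16), ncd (CG7831, a kinesin, -0.96 ± 0.21) and mei-38 (-1.13 ± 0.27). Of 17 kinetochore genes, 2 were more negative, with a median of -0.41 (6 adjusted over the list alone, 5 with the block), namely cid (CG13329, -1.66 ± 0.22) and Nuf2 (CG8902, -0.83 ± 0.18). Of 18 centrosome genes, 2 were more negative, with a median of -0.25 (2 adjusted over the list alone), namely Plp (-1.18 ± 0.18) and spd-2 (CG17286, -0.98 ± 0.15), both of the pericentriolar material and both falling in the disc and rising in S2. Of 13 condensin and cohesin genes limma called 0 (5 at an unadjusted p under 0.05, 0 adjusted over the list alone and 1 with the block), with a median of -0.18. The adjusted p was 0.000766 for mitotic regulators, 0.000323 for the spindle, 5.1e-05 for kinetochores, 0.00207 for centrosomes and 0.0272 for condensin and cohesin. In the same order these became adjusted p = 0.34, adjusted p = 0.34, adjusted p = 0.27, adjusted p = 0.46 and adjusted p = 0.49 with an estimated correlation. The condensin list lost its call without wing disc G1 array 3 (adjusted p = 0.0811), S2 G1 array 6 (adjusted p = 0.146) or S2 G2 array 6 (adjusted p = 0.0514), and the centrosome list without S2 G1 array 6 (adjusted p = 0.0911). Calls of ncd, mei-38 and Nuf2 were lost without 6, 7 and 4 of the 12 arrays in turn (highest adjusted p = 0.0603, 0.079 and 0.0578).

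Disc development genes, immune genes, markers of other cell types and oxidative phosphorylation genes made up the remaining lists that differed. Of 39 patterning genes, 7 had a more positive change in the disc (9 adjusted over the list alone) and 0 a more negative one, with a median of 0.21. eyg had 1.51 ± 0.13, pnr 0.98 ± 0.20 and ara (CG10571) 0.75 ± 0.17. Of 10 sensory organ precursor genes, ac (CG3796, 1.75 ± 0.20) and sc (CG3827, 1.35 ± 0.22) were more positive, with a median of 0.39 (4 higher and 2 lower adjusted over the list alone, and also with the block). Of 11 antimicrobial genes, Drs and Mtk were more positive, with a median of 0.42 (4 adjusted over the list alone). Of 11 tracheal genes, verm (0.74 ± 0.14), knrl (CG4761, 0.80 ± 0.20) and vvl (1.04 ± 0.27) were more positive, with a median of 0.19 (4 adjusted over the list alone). Of 9 muscle precursor genes, 4 were more negative, with a median of -1.04 (5 adjusted over the list alone), Act87E (-1.55 ± 0.18), htl (-1.41 ± 0.28) and twi (-1.13 ± 0.23) among them. Of 20 haemocyte genes, SPARC (-1.45 ± 0.17), vkg (-1.77 ± 0.31) and Col4a1 (-1.59 ± 0.33) were more negative, with a median of -0.35 (3 adjusted over the list alone). Of 58 oxidative phosphorylation genes limma called 0 (1 at an unadjusted p under 0.05), with a median of -0.08. Averaged over both fractions, 27 of the 39 patterning genes, 8 of the 10 sensory organ genes, 7 of the 11 tracheal genes and 5 of the 9 muscle precursor genes had a mean under 5 in S2, where a change is hard to see, so their differences mostly restate the disc change. Of the 11 antimicrobial genes 4 had a mean of at least 13 in S2, with array maxima of 14.80 to 14.95, which leaves little room for a rise there.

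The adjusted p was 0.000956 for patterning, 0.0272 for sensory organ precursors, 0.000766 for antimicrobial genes, 0.0119 for trachea, 0.000472 for muscle precursors, 0.0126 for haemocytes and 0.0151 for oxidative phosphorylation. With an estimated correlation the antimicrobial list had adjusted p = 0.26, the oxidative phosphorylation list adjusted p = 0.61 and the other 5 lists each adjusted p = 0.27. The call of oxidative phosphorylation was lost after cyclic loess (adjusted p = 0.0899) and without wing disc G2 array 2 (adjusted p = 0.0919) or S2 G1 array 5 (adjusted p = 0.157). The sensory organ list lost it with array weights (adjusted p = 0.13) and without S2 G1 array 5 (adjusted p = 0.0546) or array 6 (adjusted p = 0.14), and the tracheal list at the filter of 7 (adjusted p = 0.0764). Calls of ara, knrl and vvl were lost without 9, 10 and 10 of the 12 arrays in turn (highest adjusted p = 0.0735, 0.0932 and 0.107), and another probe set of vvl did not share its call. The ecdysone response list did not pass (adjusted p = 0.115), but did with the block (adjusted p = 0.0233). In all, 438 probe sets differed, 190 more positive and 248 more negative in the disc, and 106 of them had an S2 mean under 5 and 47 a disc mean under 5. The count was 949 with the block (479 and 470), 289 without wing disc G1 array 4, 281 without wing disc G2 array 4, 287 without S2 G1 array 4 and 288 without S2 G2 array 5.

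Wing disc and S2 cells, each averaged over both fractions, were compared as background for that test. The lists of disc development were higher in the disc, and the antimicrobial and haemocyte lists higher in S2. At an estimated correlation 0 of 26 lists passed (4 at an unadjusted p under 0.05), with adjusted p = 0.20 for patterning, adjusted p = 0.26 for sensory organ precursors, adjusted p = 0.39 for the Notch response, adjusted p = 0.31 for antimicrobial genes and adjusted p = 0.39 for haemocytes. ImpE2 (CG1934), an ecdysone-inducible gene, was 10.15 ± 0.13 higher in the disc (adjusted p = 1e-14), followed by obst-A (CG17052, a chitin-binding protein, 9.54 ± 0.08), CG31997 (8.97 ± 0.09), nw (CG43164, 8.78 ± 0.11), Spn43Aa (CG12172, a serpin, 8.48 ± 0.12) and Cda4 (CG32499, a chitin deacetylase, 8.21 ± 0.10). On the other side stood edin (CG32185, an immune-induced peptide, -9.97 ± 0.09, adjusted p = 1.8e-15), DptB (CG10794, a diptericin, -9.23 ± 0.06), Mtk (-9.19 ± 0.18), blanks (CG10630, -9.08 ± 0.11), CG6231 (-8.58 ± 0.19) and AttD (CG7629, an attacin, -8.55 ± 0.25). The size and order of these differences are limited by the range of the arrays. The genes higher in the disc all had means under 5 in both S2 groups (ImpE2 3.49 and 3.57, obst-A 2.46 and 2.36). The S2 means of edin, DptB, Mtk and AttD, from 14.31 to 14.61, lay near the array maxima, and edin, blanks and CG6231 were under 5 in both disc groups.

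Lists of disc identity were higher in the disc. These were patterning (32 higher and 5 lower of 39, median 3.63, for example ci at 6.93 ± 0.07 and Dr at 6.27 ± 0.09), sensory organ precursors (9 and 1 of 10, median 2.23, for example esg at 5.76 ± 0.13), the Notch response (6 and 0 of 6, median 5.71, for example E(spl)m6-BFM at 6.76 ± 0.12), muscle precursors (8 and 1 of 9, median 3.39, for example Him at 7.97 ± 0.22) and trachea (10 and 1 of 11, median 4.02, for example Gasp at 8.05 ± 0.11). Licensing genes (10 and 2 of 14, median 0.76, for example Mcm3 at 1.40 ± 0.10) and the proteasome (19 and 5 of 32, median 0.35, for example Uch-L5 at 1.33 ± 0.06, but Rpt3R at -2.19 ± 0.11) were higher as well. Higher in S2 were haemocyte genes (14 higher there and 5 lower of 20, median -2.45, for example srp, a GATA factor, at -7.64 ± 0.12, but Ppn at 5.63 ± 0.15), antimicrobial genes (9 and 1 of 11, median -5.52), ribosome biogenesis (25 and 1 of 34, median -0.45, for example Surf6 at -1.85 ± 0.07) and oxidative phosphorylation (38 and 8 of 58, median -0.33, for example Cyt-c1 at -1.19 ± 0.06). Of the genes given as examples, ci, Dr, esg, E(spl)m6-BFM, Him and Gasp were under 5 in S2 and srp in the disc. S2 means were under 5 for 27 of the 39 patterning, 8 of 10 sensory organ, 4 of 6 Notch, 5 of 9 muscle precursor and 7 of 11 tracheal genes, so that sizes and medians in these lists are limited by background. Counts adjusted over the list alone were the same in these 11 lists except for the proteasome (18 and 5). The adjusted p ran from 5.9e-08 (patterning) to 0.0365 (licensing), and with an estimated correlation from adjusted p = 0.20 (patterning and trachea) to adjusted p = 0.68 (oxidative phosphorylation), so that 0 lists passed then, with 4 at an unadjusted p under 0.05. Licensing lost its call without S2 G1 array 6 (adjusted p = 0.0564) and the proteasome after subtraction of array medians (adjusted p = 0.0518). Of 8580 probe sets 7179 differed, 3519 higher and 3660 lower in the disc, and 1465 and 1748 by at least 2-fold. With replicate number as a random block, which takes the pairing into account, 6878 differed (3338 higher and 3540 lower). Subtracting each array's median shifted the median difference of all probe sets by -0.112.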

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

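Tests of attached non-epithelial cells, of the separation of the S2 fractions, of haemocytes and of genes as abundant in S2 were chosen after the result was seen. Each result in this part was picked out because the G2 against G1 change differed between wing disc and S2 in a test of the difference itself. Values are the disc change minus the S2 change on the log2 scale.

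In all, 438 probe sets differed, 106 of them with an S2 mean under 5 and 47 with a disc mean under 5, where a change is hard to see. With 10 splits of the same-number pairs no share under 0.05 can be had, and in the fit with replicate number as a block the real split, the 1 with the most calls, gave 949 and the highest other 0. The same holds for the disc comparison (902 calls, highest other 0, 1 of 10 splits as large) and the S2 comparison (828, highest other 1, 1 of 10). For disc against S2, 1 of 100 splits gave as many as 7179 calls, with 3199 the highest other. These splits moved arrays singly although same-numbered arrays are paired, so they do not exclude chance there. List calls were 11 in the disc, where 2 of 10 splits gave as many (highest other 11, and 7 among the splits that part as many pairs), and 7 in S2, where 1 of 10 did (highest other 6). For lists, too, no share under 0.05 can be had with 10 splits.

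Replication genes fell further in the disc, with medians of -1.24 for licensing and -0.82 for the fork list. The genes were Orc1 (-2.15), Orc2 (-1.56), Orc5 (-0.83), Cdc6 (-1.83), dup (-1.81), Mcm10 (-1.45), Mcm6 (-0.82), Prim1 (-1.42), Prim2 (-1.44), Caf1-105 (-1.41), Ts (-0.97), asf1 (-0.78) and dnk (-1.12), with CG13690 (-1.25) and CG4570 (-1.30) beside them.

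Uniformly poorer separation of the S2 fractions would shrink every change. But 73 mitotic, spindle and kinetochore genes had a median difference of -0.29, that is, they rose more in S2. This argues against it only if the mitotic rise would be equal in both cell types at equal separation, which was not tested. Compression of low signals was argued against by the 22 replication genes with a mean of at least 9, whose median difference was -0.80, against -0.96 for all 46. Cyclic loess left the median of the 46 at -0.93. It was applied to the deposited RMA values and shifted the difference of all probe sets by a median of 0.025. It therefore cannot test the normalization within RMA, which stays open. Cells in S phase that enter the 2C and 4C gates in other shares in disc and S2 stay open, as does a difference between the cell types in how these genes are regulated, which was not tested.

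In the disc 5 of 9 adult muscle precursor markers fell and 4 did not pass, and Act87E (-1.55), twi (-1.13), htl (-1.41) and the list (-1.04, adjusted p = 0.000472, or adjusted p = 0.27 with an estimated correlation) differed from S2, where these 3 genes were under 5 in both fractions (3.15 to 3.86), so that the difference restates the disc fall. A loss of every kind of attached non-epithelial cell would lower the tracheal list as well, whose median disc change was 0.45. That list lacked trh and dys, which were not matched to a probe set of their own. The haemocyte list fell (median -0.42), but it is a weak measure here, since 5 of its 20 genes had a disc mean under 5. A loss of several kinds of attached cell therefore stays open. Cyclic loess of the deposited RMA values left the muscle precursor median at -1.28 (-1.23 without). It shifted the disc change of all probe sets by a median of -0.035, so it cannot test the normalization within RMA. A smaller share of muscle precursors in the G2 gate may account for it and is not ruled out by a gate on DNA content, which does not remove them (Him was 12.68 in disc G1 and 11.45 in disc G2, and Ama, which did not pass, 12.55 and 12.48). The test of 5 further genes that precursors express left this open. Their median of -0.29 was just short of the fall set beforehand as a mark of a smaller share. CadN (-0.57), LanA (-0.36), LanB2 (-0.29) and LanB1 (-0.17) were lower and Msp300 (0.44) was higher. None of the 5 passed (adjusted p from 0.071 to 0.58). Lower expression of these genes per cell in G2 was not tested.

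In the disc 4 of 11 antimicrobial genes rose, with the list not past its test there (adjusted p = 0.167), and Drs (2.20), Mtk (2.05) and the list (0.42, adjusted p = 0.000766, or adjusted p = 0.26 with an estimated correlation) differed from S2, where Drs, Mtk and AttD were at 13.69 to 14.40 against array maxima of 14.80 to 14.95, so that a rise in S2 stays open. S2 RNA carried over into disc G2 samples was argued against by 100 other genes with the largest S2 excess, whose median disc change was -0.04 (4 rose and 5 fell), although they lie near the floor in the disc. Among 4 genes as abundant in S2 as Drs, Mtk and AttD, the highest disc change was 0.58 (edin, with blanks at 0.19, DptB at 0.34 and Nplp2 at -1.32), against 1.91 for the smallest of those 3. Mtk (4.19) and AttD (4.85), like edin (4.24) and blanks (4.69), were under 5 in disc G1, so these sizes are limited. More haemocytes in the G2 fraction would raise the haemocyte list, whose median disc change was -0.42. But 5 of its 20 genes had a disc mean under 5, and srp was at 2.87 and 2.98 in disc G1 and G2. The list is therefore a weak measure of haemocytes in the disc, and this explanation stays open. With 1 disc array left out, the median of the 4 genes that rose was 1.63 at the lowest (1.93 with all). Their rise as a set therefore did not rest on 1 disc array. These genes had been chosen because they passed on the same arrays, so an aberrant array is not excluded. Fat body attached to discs stays open, since 2 of its genes were tested, and so does an immune response of disc cells, which may differ with the gate and was not tested.

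Among the mitotic lists, the medians were -0.19 (mitotic regulators), -0.28 (spindle), -0.41 (kinetochore), -0.18 (condensin and cohesin) and -0.25 (centrosome). In this order they had adjusted p = 0.34, adjusted p = 0.34, adjusted p = 0.27, adjusted p = 0.49 and adjusted p = 0.46 with an estimated correlation. Their genes were twe (-1.36, under 5 in both S2 fractions), pim (-0.87), CycB3 (-0.78), borr (-0.79), ncd (-0.96), mei-38 (-1.13), cid (-1.66), Nuf2 (-0.83), Plp (-1.18) and spd-2 (-0.98). G1/S regulators had a median of -0.31, with Rbf2 (-0.81), mip130 (-0.67) and Cdk4 (0.45), and adjusted p = 0.30 with an estimated correlation. The oxidative phosphorylation list had a median of -0.08 and adjusted p = 0.61 with an estimated correlation.

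Patterning genes had a median of 0.21, with eyg (1.51), pnr (0.98) and ara (0.75), and sensory organ precursor genes 0.39, with ac (1.75) and sc (1.35). Both lists had adjusted p = 0.27 with an estimated correlation. Tracheal genes had a median of 0.19, with verm (0.74), vvl (1.04) and knrl (0.80), and adjusted p = 0.27 with an estimated correlation. Haemocyte genes had a median of -0.35, with SPARC (-1.45), vkg (-1.77) and Col4a1 (-1.59), and also adjusted p = 0.27 with an estimated correlation. Of the genes named, eyg, ara, ac, sc, vvl and knrl were under 5 in both S2 fractions and verm was close to it (5.06 and 5.00), so that their differences restate the disc change. Other genes were CG13023 (3.47), CG15353 (3.34), Ect3 (2.86), slf (2.00), TwdlT (1.86), spidey (-1.97), jumu (-1.90), CG9593 (-1.87) and Sox100B (-1.84). The same holds for CG13023, CG15353, slf, TwdlT, CG9593 and Sox100B, under 5 in both S2 fractions, and Ect3 was close to it (5.05 and 4.77).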

How the results depend on the processing

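Camera with an estimated correlation in the fit with the replicate block was chosen after seeing the data. With array weights the counts were 2043 (disc), 1645 (S2) and 1151 (difference), with 533 shared, and with the replicate block 1626, 1577 and 949, with 471 shared. The block kept 897 of 902, 822 of 828 and 432 of 438 of the calls. In fits of 1 cell type S2 gave 413 calls, 124 shared. The cause was not tested. The total counts of calls and of shared changes stayed within 1.5 times under median subtraction, cyclic loess, no filter, the filter at 7, a trended variance and 1 probe set per gene, while shared rises went from 100 to 64 with no filter. Leaving out each array gave 601 to 1152 in the disc, 493 to 1088 in S2, 281 to 586 for the difference, 7009 to 7193 for disc against S2 and 138 to 266 shared. Each of these highest counts came without S2 G1 array 6. List calls were 11, 7, 15 and 11 in the 4 contrasts, and 9 to 11, 5 to 7, 11 to 16 and 10 to 11 with arrays left out. With an estimated correlation they were 2, 0, 2 and 0 (5, 2, 4 and 4 at an unadjusted p under 0.05), and with the block as well 0, 0 and 0 in the first 3 contrasts (2, 1 and 2 unadjusted). The lists that held with an estimated correlation were licensing and the replication fork, in the disc and in the difference. The disc list of cytosolic ribosomal proteins turned in direction after cyclic loess (adjusted p = 0.584), and the cause was not tested. Of 172 results for named genes 0 turned in direction. The most that lost their call under 1 of these settings were 6 (no filter), and over the arrays left out in turn 1967 were the same, 94 lost their call and 3 gained it. The block changed the calls of CycB in the disc and of CycE and PCNA in the difference, and of the G1/S list in the disc and the ecdysone list in the difference. It changed no other list call in the first 3 contrasts, the only ones in which lists were tested with the block. No other call of a gene chosen by the ranking rule or as a sort check changed. Other genes given as examples, such as RfC3 in the disc (31 of the fork list lower with the block), could gain one. Dim probe sets limit what could be seen: 8580 of 18769 reached a value of 5 on 3 arrays.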

Other observations

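The tests of gene families in this part were chosen after seeing the data. Families of at least 6 genes that share the start of their symbol were compared with all other genes, 60 families in each of the 2 fraction contrasts and in the difference, and 3 of these tests passed. With an estimated correlation none of the 3 did. Nucleoporin genes (symbols starting with Nup), which encode the nuclear pore complex, were lower in disc G2 at the preset correlation (adjusted p = 6.72e-07, or adjusted p = 0.945 with an estimated correlation). Of 20 genes, 9 fell, 0 rose and the median change was -0.28. The falls included Nup160 (-0.67 ± 0.16), Nup93-1 (-0.59 ± 0.11), Nup54 (-0.59 ± 0.10) and Nup43 (-0.58 ± 0.09). The direction held after subtraction of array medians (median -0.25, with 8 lower) and cyclic loess (median -0.31, with 9 lower). In S2, 2 of the 20 fell (Nup43 and Nup37) and the family did not pass (adjusted p = 0.197), nor did the difference between disc and S2 (adjusted p = 0.0513).

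In S2 G2 the dgt genes, most of which encode augmin subunits, were higher at the preset correlation (adjusted p = 0.00195, or adjusted p = 0.228 with an estimated correlation). Of 6 genes, 5 of them in the spindle list as well, 4 rose (dgt2, dgt3, dgt5 and dgt6), with a median of 0.62, or 0.66 after subtraction of array medians and 0.55 after cyclic loess. The glutathione transferase genes of the GstE group were lower in S2 G2 (adjusted p = 0.0312, or adjusted p = 0.797 with an estimated correlation). Of 11 genes, 1 fell (GstE12, -0.27 ± 0.07, against 4 with the replicate block, a call that was lost after subtraction of array medians), with a median of -0.27, or -0.23 after subtraction of array medians and -0.31 after cyclic loess.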
